A study of Mus musculus with 3 samples.

How the data were processed

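Small RNAs of mature sperm, adult testis and adult uterus of CD1 mice were measured by high-throughput sequencing, with 1 library per group. Per the labels' protocols, small RNA was ligated to adapters at both ends, reverse transcribed, amplified by PCR and sequenced, and sperm were treated with a lysis buffer against somatic cells. The deposited tables list distinct read sequences with their counts, which are whole numbers and were not normalized by the authors as far as the values show. The submitters' processing notes name the genome build mm9; the adapter trimming, the size range taken and the tools are not given in the sources used here. The tables held reads of 18 to 44 nt. The tables of sperm and testis each ended with 1 line that holds no sequence, which was left out.

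All sequences and counts were used as deposited. Depth was 15690722 reads for sperm, 23783785 for testis and 15876066 for uterus, so that a count of 0, taken as at most 3 counts, allows up to 0.189 reads per 1000000 in uterus. Groups follow the source named in the labels. With 1 library per group no test, standard error or p-value was computed. Shares have exact Clopper-Pearson 95% intervals, reads per 1000000 (RPM) exact Poisson 95% intervals, and ratios of counts conditional exact binomial 95% intervals. A ratio against 0 reads was computed with 3 counts in place of 0 and is a bound. No ratio was formed where both counts were at most 3.

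Reads were matched without a genome, since only transcripts and annotation of GENCODE M21 (GRCm38) and a gene table of GRCm38.p6 were used. Coordinates are those of GRCm38 and were not converted to mm9. The 27 nuclear tRNA sequences of 25 families were written from general knowledge before the data were examined and could not be checked against a genome; the gene table holds 430 tRNA genes by name without sequence. A read was a tRNA read if it matched a listed tRNA with its CCA tail exactly in sense, a 5′ read if it began at base 1 to 3, and a 3′ read if it ended within the last 3 bases or in CCA. A read that matched several families was counted once, for the set of families. Reads with 1 substitution or 1 deletion of 1 to 3 bases were kept apart, as were tRNA-His reads with an added G. Mitochondrial tRNAs were the 22 of GENCODE. A microRNA read shared its first 20 bases with 1 of 71 listed mature microRNAs, all of which matched a GENCODE hairpin. Ratios between libraries used reads per 1000000 listed microRNA reads, and microRNAs with at least 100 reads in the higher library were counted as at least 4-fold apart or not. The piRNA-length class held reads of 26 to 31 nt without an exact match to a listed or mitochondrial tRNA or to annotated ribosomal RNA. Reads of listed microRNAs were left out as well. The class was summed per GENCODE gene in place of genomic windows.

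The 12 microRNA lists (germ cell, X-linked testis, smooth muscle, erythroid, leukocyte, epithelial, endothelial, let-7, miR-17-92, Hox cluster, the miR-99, miR-100 and miR-125 group, and a negative control) were fixed before the data were examined. A list's median was placed among 10000 random lists of the same size, matched on mean expression and drawn from 246 microRNAs with at least 100 reads, as a description of these libraries. Named items follow a rule fixed beforehand: the 10 tRNA families with most 5′ reads in sperm with their leading fragment (1 leading fragment is not reported here); members of the lists, the 8 most abundant microRNAs of each library and the 8 largest ratios in each direction; and the 5 leading piRNA-length sequences and genes in testis.

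Alternatives changed 1 choice at a time: distinct sequences in place of reads, leaving out sequences with a single read, other length windows, match rules and denominators, TMM factors of edgeR 4.0.16 and size factors of DESeq2 1.42.0 computed over the listed microRNAs, and other count minimums. Ratios of tRNA families with altered reads, ratios of piRNA-length sequences and genes as shares of their class, and DESeq2 size factors for list medians were added after the data were seen. The genome-matched alternatives were replaced by reads up to 35 nt or not run. Matching and ratio steps were tested on simulated data. Of simulated 5′ tRNA reads, 100% of 303 exact ones, 100% of 399 with a substitution and 99.2% of 395 with a deletion were assigned to their class. For simulated 8-fold changes among 898 hairpin arms, the 4-fold rule called 100% of the 30 changed arms that had enough reads for sperm and testis, 91.0% of 78 for sperm and uterus and 75.4% of 69 for testis and uterus. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3, were used.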

Results

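Small RNAs were sequenced from mature sperm, adult testis and adult uterus of CD1 mice, an outbred laboratory strain. The sperm had been released from the cauda epididymis, the storage end of the duct that leads away from the testis, and kept in a buffer that lyses somatic cells before RNA was taken. Each group had 1 library, so no difference below has a replicate check and no test between groups was made. The libraries held 15690722 reads for sperm, 23783785 for testis and 15876066 for uterus, all of 18 to 44 nt. All intervals are 95% intervals that cover counting error only, since reads amplified by PCR are not independent molecules.

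The testis library was the most diverse. Thinned to the depth of the sperm library, it held 1953804 distinct sequences, against 1302963 in sperm and 521397 in uterus. The 10 most abundant sequences took 37.9% of the reads in sperm, 4.63% in testis and 49.8% in uterus, and the 100 most abundant took 58.3%, 13.3% and 71.3%. Among distinct sequences, 71.2% in sperm, 67.8% in testis and 78.1% in uterus had a single read. In uterus the leading sequence was let-7c or a form trimmed from it, with 15.0% of all reads.

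The first comparison asks which sizes of small RNA each source contains. Sperm reads peaked at 32 nt, which held 20.8% of the library, testis reads at 30 nt with 31.4%, and uterus reads at 22 nt with 52.5%. Reads of 29 to 34 nt made up 69.0% of sperm (68.97 to 69.02%) and 79.5% of testis (79.52 to 79.55%), but 0.427% of uterus (0.424 to 0.431%). Reads of 21 to 23 nt, the length of microRNAs, made up 6.19% of sperm (6.18 to 6.20%), 1.35% of testis (1.34 to 1.35%) and 80.1% of uterus (80.11 to 80.15%). Only sperm had a sizeable tail above 34 nt, with 12.4% of its reads, against 0.231% in testis and 0.00142% in uterus. The size range cut from each RNA sample is not given in the sources used here, so the near absence of reads above 28 nt in uterus (0.429%) and of reads under 24 nt in testis (1.45%) limits every comparison of a long class with a short class between libraries.

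**Figure D1:**
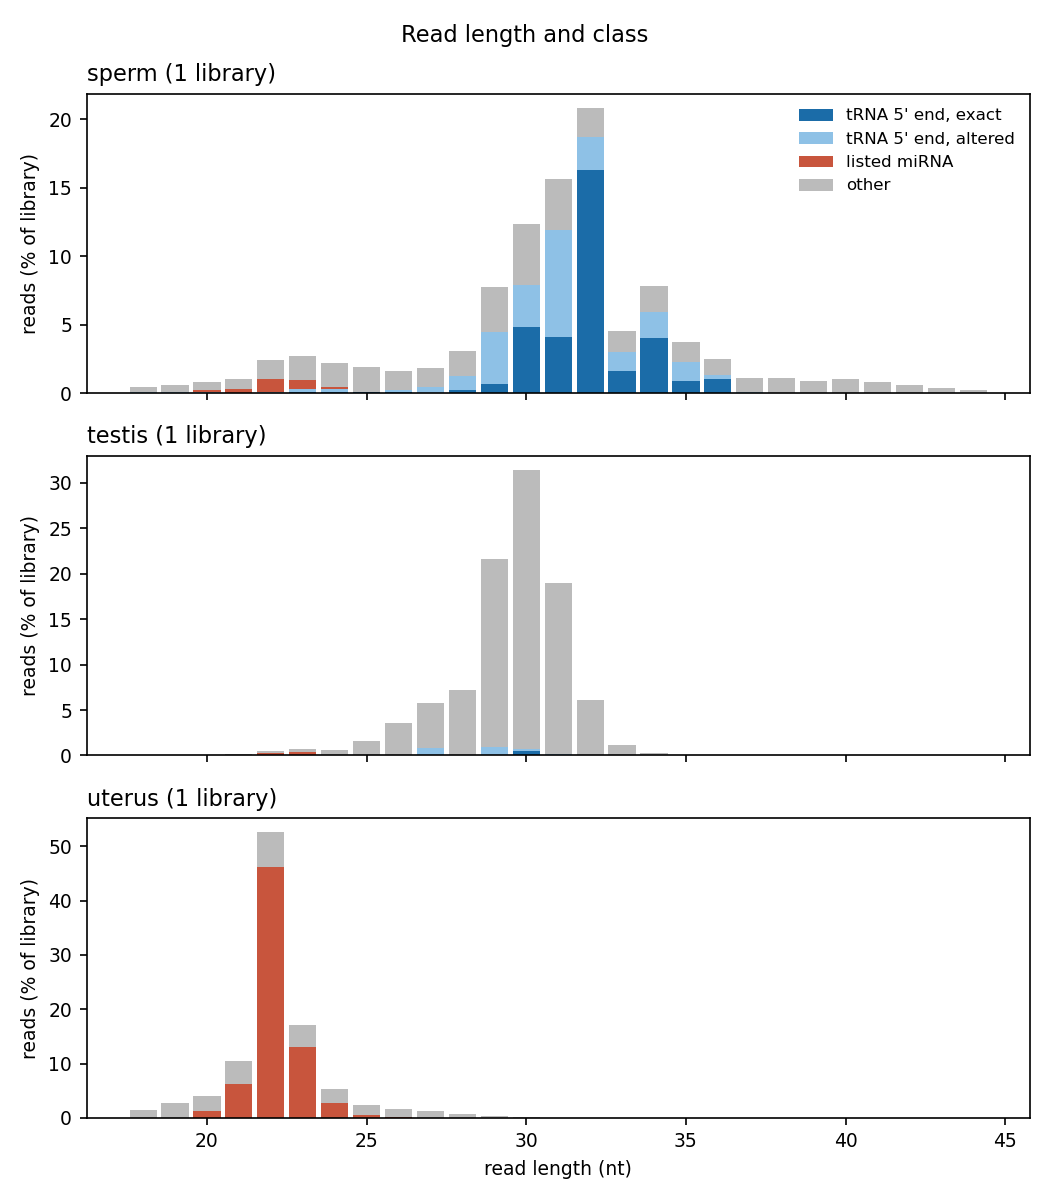
Share of each library's reads (vertical axis, % of library) at each read length (horizontal axis, nt) in sperm, testis and uterus, 1 library each, with bars divided into exact 5′ tRNA reads, 5′ tRNA reads with 1 substitution or deletion or an added G, listed microRNAs and all other reads. Sperm peaks at 32 nt with mostly tRNA reads, testis at 30 nt with mostly other reads and uterus at 22 nt with mostly microRNA reads.

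The second comparison concerns fragments of transfer RNAs, the adaptors that carry amino acids to the ribosome. Fragments from the 5′ end of tRNAs were abundant in sperm and scarce in both tissues. Reads that matched a listed tRNA exactly and began within its first 3 bases made up 34.1% of the sperm library (34.04 to 34.09%), 0.507% of testis (0.504 to 0.510%) and 0.0255% of uterus (0.0247 to 0.0263%). The share in sperm was 67.1 times that in testis (66.8 to 67.5) and 1335 times that in uterus (1295 to 1377), and the share in testis was 19.9 times that in uterus. In sperm 92.2% of these reads were 29 to 34 nt long, against 2.74% in uterus.

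The 3′ ends of the same tRNAs were rare in all libraries, at 0.164% of reads in sperm, 0.00492% in testis and 0.0535% in uterus. Reads from 5′ ends outnumbered those from 3′ ends by 207 times in sperm (205 to 210) and by 103 times in testis (97.4 to 109). In uterus the ratio was 0.477 (0.459 to 0.495), so 3′ ends were the more frequent among the reads of that library. Only 0.429% of its reads were longer than 28 nt, so long 5′ fragments may be missing from this ratio. Mitochondrial tRNA reads were also higher in sperm, at 0.177% of reads against 0.00164% in testis and 0.00140% in uterus. Exact matches to annotated ribosomal RNA made up 0.833% of sperm, 0.00403% of testis and 0.0474% of uterus.

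Exact matching set the level of the tRNA share. When reads with 1 substitution, 1 deletion of 1 to 3 bases or, for tRNA-His, an added G were included, an alternative chosen after the data were seen, the 5′ share rose to 58.7% in sperm, 2.81% in testis and 0.0512% in uterus, and the ratio of sperm to testis fell from 67.1 to 20.9 (20.8 to 20.9). The list of 27 tRNA sequences covers 25 anticodon families and lacks others, so the exact shares are lower bounds. The shares with altered reads are not, since the origin of the altered reads is open.

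A few tRNA families supplied nearly all 5′ fragments in sperm. tRNA-Glu-CTC gave 62.6% of them, with 213130 reads per 1000000 reads (RPM; 212901 to 213358), against 4885 in testis (4857 to 4914) and 24.7 in uterus (22.3 to 27.3). Fragments shared by tRNA-Gly-CCC and tRNA-Gly-GCC gave 21.2%, and longer ones specific to tRNA-Gly-GCC gave 10.1%. The 10 leading family sets together held 98.9%, and each of the 10 was higher in sperm than in testis, by 43.6 to 14204 times, and higher than in uterus, by at least 138 times. With altered reads and the added G included, and shared fragments counted for Gly-GCC and Val-CAC, the 8 families Glu-CTC, Gly-GCC, Glu-TTC, Val-CAC, Leu-CAG, Cys-GCA, His-GTG and iMet-CAT were 12.8 to 7945 times as frequent in sperm as in testis and at least 111 times as frequent as in uterus. Among families outside the 10 sets, named after their values were seen, tRNA-Ala-AGC then reached 5198 RPM in sperm, 38.7 times that in uterus (37.04 to 40.4), and tRNA-Lys-TTT was only 4.83 times as frequent in sperm as in uterus (4.57 to 5.12).

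The leading fragment shared by both glycine tRNAs was GCATTGGTGGTTCAGTGGTAGAATTCTCGC, bases 1 to 30 of the tRNA, with 643057 reads in sperm, 15 in testis and 0 in uterus. For tRNA-Gly-GCC alone it was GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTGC, bases 1 to 34, with 472739 reads in sperm, 104 in testis and 0 in uterus. Fragments long enough to be specific to Gly-GCC numbered 542120 in sperm, 153 in testis and 0 in uterus, a library with few reads of that length. The shorter ones shared with Gly-CCC numbered 1133889, 121 and 474, a ratio of sperm to uterus of 2420 (2212 to 2654). The specific fragments were 5371 times as frequent in sperm as in testis (4584 to 6335), whereas Glu-CTC fragments, the only family above 1000 RPM in testis, were 43.6 times as frequent (43.4 to 43.9), or 12.8 times with altered reads (12.79 to 12.86).

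Other families followed at lower levels in sperm. tRNA-Glu-TTC reached 5099 RPM, with a leading fragment of bases 1 to 31, and tRNA-Val-AAC and tRNA-Val-CAC shared fragments at 3200, led by bases 1 to 33. tRNA-Leu-CAG stood at 3175 (bases 1 to 35), tRNA-Cys-GCA at 2189 (bases 1 to 34), fragments specific to tRNA-Val-CAC at 2055 (bases 1 to 34), tRNA-His-GTG at 732 (bases 1 to 34) and the initiator tRNA-iMet-CAT at 647 (bases 1 to 30). The value of tRNA-His-GTG rose to 7015 with altered reads and those with the added G, which the listed sequence lacks. Among the 10 sets, tRNA-Glu-TTC and tRNA-iMet-CAT were nearest to testis after Glu-CTC, at ratios of 44.6 (43.0 to 46.4) and 52.0 (46.3 to 58.5), or 25.2 and 41.8 with altered reads. Genomic positions of the nuclear tRNA fragments are not given, since no genome sequence was used here; the annotation table for GRCm38.p6 names 12 genes for Glu-CTC and 14 for Gly-GCC.

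**Figure D2:**
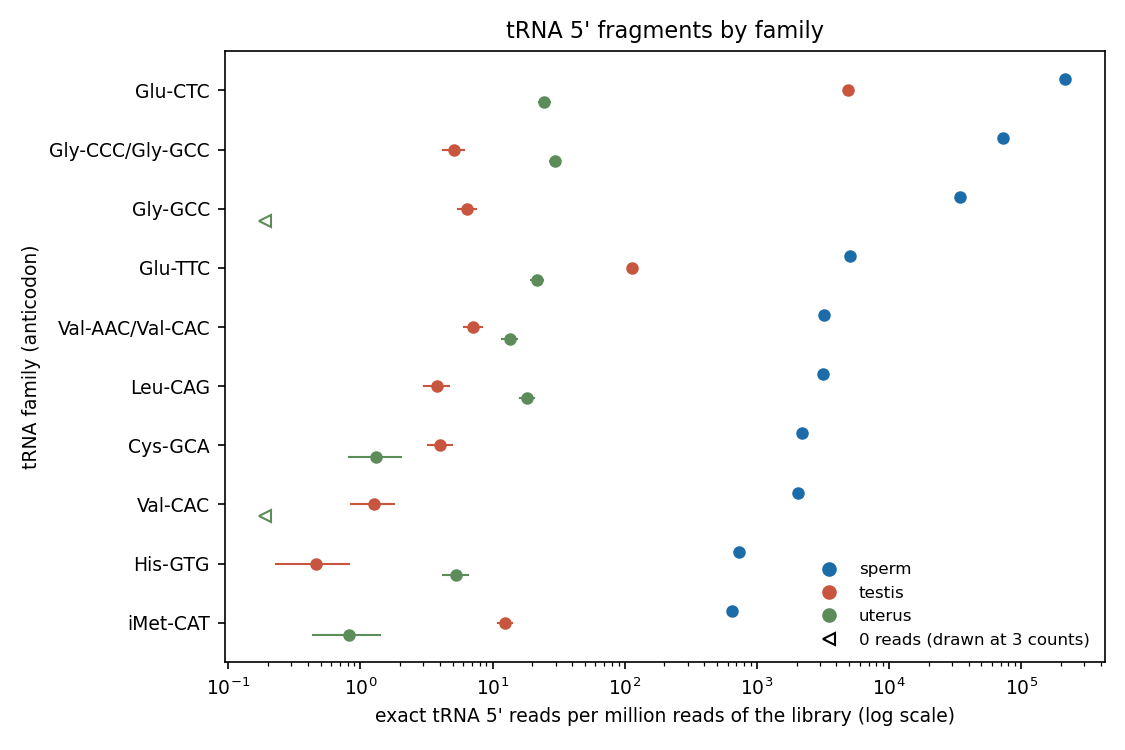
Exact 5′ tRNA reads per 1000000 reads of the library (horizontal axis, log scale) for the 10 tRNA family sets with most reads in sperm (vertical axis), with exact Poisson 95% intervals as lines and open triangles for 0 reads, drawn at 3 counts. All 10 sperm points lie to the right of both tissues, and Glu-CTC has the highest level in testis at 4885.

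The third comparison concerns microRNAs. They dominated the uterus library and were a small part of the others. Reads that began with the first 20 bases of 71 listed mature microRNAs made up 70.0% of uterus (69.94 to 69.99%), 2.20% of sperm (2.19 to 2.21%) and 0.758% of testis (0.754 to 0.761%). Members of the let-7 family, microRNAs that accumulate in differentiated tissue, alone made up 59.7% of the uterus library, 0.794% of sperm and 0.277% of testis. Reads of 20 to 24 nt on any annotated microRNA hairpin, used in place of the list, made up 65.3% of uterus, 2.51% of sperm and 0.784% of testis. Among only the reads that match an annotated RNA, the order of sperm and testis turned, with a microRNA share of 4.99% in sperm and 6.22% in testis.

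The leading microRNAs differed between the libraries. In testis miR-34c-5p, a microRNA of meiotic and later male germ cells, held 50.0% of the listed microRNA reads, followed by let-7f-5p with 12.9%. In sperm let-7c-5p led with 14.5%, followed by miR-200c-3p with 10.4%, miR-143-3p with 9.02%, let-7f-5p with 8.31%, let-7a-5p with 7.40%, miR-21a-5p with 7.37%, miR-10a-5p with 7.10% and miR-184-3p with 5.33%. In uterus let-7c-5p held 31.8%, let-7f-5p 21.5%, let-7b-5p 13.7% and let-7a-5p 12.6%, followed by miR-1a-3p with 5.503% and miR-199a-3p with 4.13%. The let-7 family held 85.4% of the listed reads in uterus, 36.1% in sperm and 36.6% in testis. In the mouse assembly GRCm38 the Mir34c hairpin lies on chromosome 9 from 51103034 to 51103110, Mir200c on chromosome 6 from 124718322 to 124718390 and Mir10a on chromosome 11 from 96317165 to 96317274.

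Ratios of single microRNAs are of reads per 1000000 listed microRNA reads. With all reads of a library as the denominator, each log2 ratio shifts by 1.54 for sperm over testis, −4.99 for sperm over uterus and −6.53 for testis over uterus. The edgeR TMM factors shift them by −0.31, −0.92 and −0.61, and the DESeq2 size factors by −1.22, −2.24 and −1.03.

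Sperm and testis were compared to see which microRNAs of the testis are found in mature sperm. Most members of the germ cell list were lower in sperm, and microRNAs of the miR-200 family and of the Hox clusters were higher. Of 59 microRNAs with at least 100 reads in either library, 20 were at least 4-fold higher in sperm and 6 at least 4-fold higher in testis. The split was 32 and 5 with all reads as the denominator and 16 and 16 with DESeq2 size factors.

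Of the 5 germ cell microRNAs, miR-34c-5p (log2 ratio −3.35, −3.38 to −3.33), miR-34b-5p (−5.89, −6.33 to −5.47), miR-449a-5p (−5.45, −5.96 to −4.99) and miR-202-5p were more than 4-fold lower in sperm. miR-202-5p, a gonadal microRNA, had 2492 reads in testis and 2 in sperm, a log2 ratio of −11.22 (−14.27 to −9.37). The fifth, miR-184-3p, was higher in sperm by a log2 ratio of 3.35 (3.25 to 3.44). The list's median of −5.45 lay below all of 10000 random lists of the same size matched on mean expression (percentile 0). Outside the lists, miR-34a-5p, of the same family as miR-34c, was also lower (−5.08, −6.01 to −4.28), and miR-21a-5p was higher in sperm (4.82, 4.69 to 4.96).

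Of the 7 epithelial microRNAs, 6 were at least 4-fold higher in sperm, with a list median of 5.22 at percentile 99.9. miR-200c-3p had 36061 reads in sperm and 10 in testis, a ratio of 1882 (1024 to 3926) and a log2 ratio of 10.88. miR-200b-3p followed at 8.67 (7.31 to 10.54), miR-141-3p at 8.14 (5.66 to 13.45) and miR-200a-3p at 5.22 (4.49 to 6.07). All 4 Hox cluster microRNAs were higher in sperm, with a median of 6.29 at percentile 99.2: miR-10a-5p at 6.67 (6.41 to 6.93), miR-196b-5p at 6.39 (5.03 to 8.27), miR-196a-5p at 6.19 (4.64 to 8.48) and miR-10b-5p at 4.59 (4.44 to 4.73). These 2 lists kept their sign under every scaling tried.

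Leukocyte and endothelial markers differed in the same direction. The epithelial, leukocyte, endothelial, erythroid and smooth muscle lists also served as markers of other cell types in the sperm and testis preparations. Whether the listed microRNAs that were higher in sperm came from sperm or from such cells was not tested. The 2 leukocyte microRNAs with at least 100 reads were at least 4-fold higher in sperm: miR-146a-5p had 1551 reads in sperm and 39 in testis (4.38, 3.92 to 4.87), and miR-150-5p had 105 and 4 (3.78, 2.38 to 5.68). The median over all 5 members was a lower bound of 3.781, set by miR-142a-3p with 79 reads in sperm and 0 in testis, and the 3 members with at least 100 reads over the libraries together had a median of 4.11 at percentile 99.5. The endothelial microRNA miR-126a-3p had 139 reads in sperm and 1 in testis (6.18, 3.68 to 11.49). The erythroid list, by contrast, had a median of −0.08 from 2 measured members, which turned to 1.46 with all reads as the denominator, and the smooth muscle list a median of −0.11, which turned to 1.43. Within the smooth muscle list miR-143-3p was higher in sperm (3.55, 3.47 to 3.63) and miR-199a-3p lower (−1.81, −1.99 to −1.62).

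In 4 further lists the sign of the median between sperm and testis depended on the scaling. The 8 X-linked testis microRNAs had a median of −0.71 (0.83 with all reads as the denominator), from −2.17 for miR-463-5p to 1.85 for miR-465a-5p. The let-7 list had a median of −0.78 (0.76 with all reads), miR-17-92 −0.33 (1.21 with all reads) and the miR-99, miR-100 and miR-125 list 0.99 (−0.23 with DESeq2 size factors). The negative control list of tissue-restricted microRNAs had 2 measured members, miR-124-3p, a neuronal microRNA with 176 reads in testis and 2 in sperm, at −7.40 (−10.45 to −5.52), and miR-9-5p at 1.06 (0.44 to 1.73), with a median of −3.17 that stayed below 0 under every scaling.

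Sperm and uterus were compared because uterus is a tissue without germ cells. X-linked testis microRNAs were present in sperm and not seen in uterus, and miR-199a-3p and let-7e-5p were higher in uterus. Of 61 microRNAs, 36 were at least 4-fold higher in sperm and 4 in uterus. The split turned to 12 and 30 with all reads as the denominator, and was 33 and 10 with TMM factors and 21 and 16 with DESeq2 size factors.

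All 8 X-linked microRNAs had 0 reads in uterus, among 11107934 listed microRNA reads. miR-465a-5p had 1496 reads in sperm, at least 16044-fold higher there, and miR-881-3p had 934, at least 10017-fold higher. The list's median log2 ratio, with each member at its lower bound, was 13.08 at percentile 100, and it stayed above 0 under every scaling. The 4 measured germ cell microRNAs had a median of 5.97 at percentile 86.8, with miR-184-3p at 11.86 (11.64 to 12.10) and miR-34c-5p at 6.46 (6.42 to 6.50). This median stayed above 0 under every scaling, but the lowest member, at 3.91, would turn with the shift of −4.99 from all reads. The epithelial list had a median of 6.31 (percentile 93.4), the leukocyte list 5.55 (percentile 97.0) and the endothelial microRNA 5.57, all above 0 under every scaling. The negative control list, with 2 measured members, lay at percentile 92.3, so the germ cell and epithelial ranks do not stand out from it. miR-200c-3p alone reached 9.71 (9.63 to 9.79).

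The let-7 list had a median of −1.37 and the smooth muscle list one of −1.32, both below 0 under every scaling. The largest ratios toward uterus were those of miR-199a-3p (−5.24, −5.39 to −5.10), let-7e-5p (−3.79, −3.92 to −3.66), miR-1a-3p, a muscle microRNA (−2.54, −2.59 to −2.49), and let-7d-5p (−2.20, −2.30 to −2.11). The Hox cluster median of 4.78 turned to −0.21, the miR-17-92 median of 4.18 to −0.81, the erythroid median of 2.07 to −2.92 and the negative control median of 3.80 to −1.19 with all reads as the denominator. The erythroid median also turned with DESeq2 size factors, to −0.18. It is that of miR-144-3p, which had 0 reads in sperm, and is an upper bound. The miR-99, miR-100 and miR-125 list had a median of 0.55, which turned to −0.37 with TMM factors.

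Testis and uterus differed in the same germ cell groups. All 5 germ cell microRNAs and the 7 X-linked ones with at least 100 reads were at least 4-fold higher in testis. The medians over all members of both lists, 9.82 and 12.09 at percentiles 99.4 and 100, stayed above 0 under every scaling. miR-202-5p had 2492 reads in testis and 0 in uterus, at least 51197-fold higher, and miR-34c-5p had a log2 ratio of 9.82 (9.78 to 9.85). Of 60 microRNAs, 20 were at least 4-fold higher in testis and 10 in uterus. The split was 12 and 43 with all reads as the denominator and 18 and 17 with DESeq2 size factors.

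Toward uterus, miR-196b-5p (−4.66, −6.53 to −3.30), miR-214-3p (−3.998, −7.05 to −2.14), miR-199a-3p (−3.44, −3.55 to −3.33) and miR-10a-5p (−2.66, −2.92 to −2.41) had the largest ratios. The smooth muscle median was −1.49, let-7 −1.22, Hox cluster −1.65, epithelial −0.14, endothelial −0.61 and the miR-99, miR-100 and miR-125 list −0.63, all below 0 under every scaling. The miR-17-92 median of 4.83 turned to −1.70, the leukocyte median of 1.78 to −4.75 and the erythroid median of 1.42 to −5.11 with all reads as the denominator. The negative control list had a median of 7.70 at percentile 97.8, with miR-124-3p at 11.82 (10.25 to 14.11), and stayed above 0 under every scaling.

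**Figure D3:**
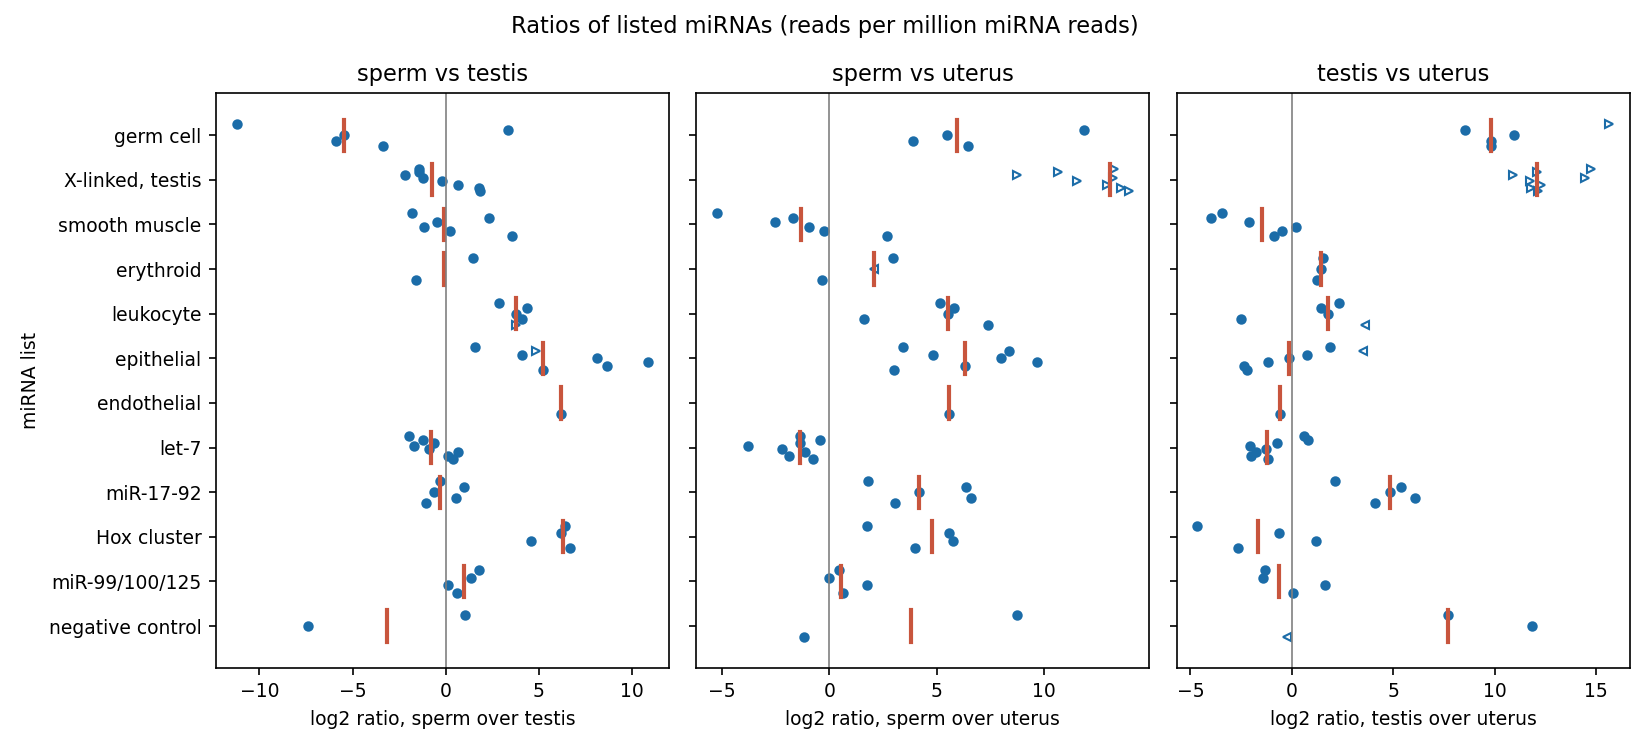
Log2 ratio of reads per 1000000 listed microRNA reads (horizontal axis) for each member of 12 lists (vertical axis) between each pair of libraries, with vertical bars at list medians, and open triangles for ratios against 0 reads, which are bounds computed with 3 counts. The epithelial and Hox cluster lists lie to the right of 0 for sperm over testis, with medians of 5.22 and 6.29, and the X-linked list lies far to the right against uterus; with all reads of the library as the denominator the points shift by 1.54, −4.99 and −6.53, which turns the sign of the Hox cluster median for sperm over uterus.

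The last comparison concerns reads of the length of piRNAs, the 24 to 33 nt class that guides PIWI proteins in male germ cells and often begins with U. Testis held most of them. Reads of 26 to 31 nt that matched no listed or mitochondrial tRNA, listed microRNA or annotated ribosomal RNA made up 88.0% of testis, 32.1% of sperm and 3.85% of uterus. Of these, 91.7% in testis (91.70 to 91.72%), 65.7% in sperm (65.61 to 65.69%) and 19.0% in uterus (18.92 to 19.11%) began with U, and 34.6%, 12.9% and 28.2% had A at base 10. Without reads that matched a tRNA with 1 substitution or deletion, the class shrank to 15.7% of sperm, with 63.9% starting with U and 26.1% with A at base 10, and stayed at 85.8% of testis.

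The 5 most abundant testis sequences of this narrower class were lower in sperm in RPM and not seen in uterus. They were ranked by testis reads, a choice that itself favours ratios toward testis. The leading sequence, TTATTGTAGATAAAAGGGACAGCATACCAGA, had 125865 reads in testis and 9354 in sperm, 8.88 times as many in testis in RPM (8.69 to 9.07). The others of the 5 most abundant were TCTGCAGGCAGAACACTTGGATTCCTCTCT, 347 times as frequent in testis (296 to 408), TGGATGTGAGATAGATAGGAGAAGGAAGTC, 3.93 times (3.86 to 4.002), TAAGATATCGTAGGACATGGTACACGGTT, 159 times (141 to 179), and TTATTGTAGATAAAAGGGACAGCATACCAG, 22.0 times (21.03 to 23.004). As shares of the class, which was itself larger in testis, these 5 ratios were 1.62, 63.3, 0.717 (0.704 to 0.731), 29.1 and 4.02, so that the third sequence held the larger share in sperm. All 5 had 0 reads in uterus, which allows at most 0.189 RPM. None of the 5 matched an annotated transcript exactly.

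Among annotated genes, again without near tRNA matches, 9.10% of the class in testis and 9.07% in sperm matched a GENCODE transcript in sense. The leading genes in testis were the noncoding RNA genes Gm21269 (chromosome 7, 73816546 to 73838898, plus strand in GRCm38), with 211292 reads in testis, 12148 in sperm and 0 in uterus, and Gm49794 (chromosome 17, 27354111 to 27367492), with 134835, 7924 and 0. Gm5878 (chromosome 6, 85111416 to 85126125), 1700001L05Rik (chromosome 15, 83353847 to 83367282) and 4933440M02Rik (chromosome 7, 125284025 to 125349788) followed. These genes, too, were ranked by testis reads. In RPM, testis exceeded sperm 11.5 times for Gm21269 (11.3 to 11.7), 11.2 times for Gm49794 (10.97 to 11.48), 3.93 times for Gm5878 (3.86 to 4.01), 8.64 times for 1700001L05Rik (8.38 to 8.91) and 11.2 times for 4933440M02Rik (10.8 to 11.6). As shares of the class the ratios were 2.10 (2.06 to 2.13), 2.05 (2.005 to 2.10), 0.718 (0.705 to 0.732), 1.58 (1.53 to 1.63) and 2.05 (1.98 to 2.12), so that Gm5878 held the larger share in sperm. Without a genome sequence, reads from unannotated clusters could not be placed, and 85.5% of the testis library matched none of the sequences used here.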

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

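Among the tests in this part, all were chosen after the altered tRNA reads had been seen. Reads outside the exact tRNA matches held a signal above the limit that a count of 0 allows in each library. Reads from tRNA 5′ ends with 1 substitution or 1 deletion of 1 to 3 bases made up 23.999% of the sperm library, 2.31% of testis and 0.0200% of uterus. Reads of tRNA-His with a G added before base 1, the base that the cell adds to this tRNA after transcription, numbered 97085 in sperm, 8 in testis and 912 in uterus, and in sperm they outnumbered the 11485 exact tRNA-His 5′ reads.

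The alterations sat at few bases, counted from 1 at the 5′ end of the tRNA. In tRNA-Glu-CTC 39.7% of the 5′ reads in sperm, 82.3% in testis and 22.4% in uterus were altered. A deletion of 1 base at or before base 7 accounted for 24.5% of the Glu-CTC reads that began at base 1 in sperm and 37.0% in testis, and a deletion of 3 bases at or before base 9 for 8.74% and 35.4%. In tRNA-Gly-GCC in sperm, G6T stood in 17.0% of these reads and a deletion of 1 base at or before base 7 in 13.9%. Some other tRNAs were altered at the same bases in sperm. C6T stood in 25.0% of tRNA-Glu-TTC reads, and G6T in 25.98% of tRNA-Gly-TCC and 9.57% of tRNA-Asp-GTC reads. In tRNA-iMet-CAT reads G9T stood in 17.6%, beside G9C in 7.37% and G9A in 6.93%. Others had few altered reads at bases 6 and 9. The shares there were 0.0933% and 0.0751% in tRNA-Val-CAC, 0.536% and 0.0134% in tRNA-Leu-CAG, and 0.556% and 0.0256% in tRNA-Cys-GCA. For tRNA-His-GTG they were 1.48% and 0.106%, and for tRNA-Lys-CTT 3.21% and 0.0227%. Some tRNAs had positions further along, such as G27T in 47.9% of tRNA-Leu-CAG, T16G in 22.7% of tRNA-Cys-GCA and G20T in 16.1% of tRNA-Asp-GTC reads. In tRNA-Ala-AGC 91.9% of the 5′ reads in sperm, 94.8% in testis and 85.8% in uterus were altered, and in tRNA-Pro-AGG 89.1% in sperm.

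For tRNA-Glu-CTC and tRNA-Gly-GCC the tables argue against random sequencing or PCR error, which would spread along the read: the mean altered share per base over bases 5 to 9 was 94.3 times the median over bases 10 to 26 in tRNA-Glu-CTC in sperm, the smallest ratio that could be formed for both tRNAs in sperm and testis. They also argue against an error in these 2 listed sequences, since at least 16.4% of the reads of each matched exactly in each library (60.3% and 58.1% in sperm); for tRNA-Ala-AGC and tRNA-Pro-AGG such an error stays open. tRNA gene copies outside the list, with tRNA-like repeats among them, stay open: over bases 5 to 9, 5 altered forms in tRNA-Gly-GCC and 2 in tRNA-Glu-CTC each held over 1% of the sperm reads, fewer than the 14 and 12 annotated genes, and no genome was used to look for them. A modified base misread by reverse transcription also stays open, since the second wrong base at base 6 of tRNA-Gly-GCC was 1.97% of the substitutions there, unlike the mixed bases at base 9 of tRNA-iMet-CAT, where it was 23.1%. The 2 open explanations cannot be told apart here, and a difference between tissues was not tested.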

How the results depend on the processing

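The alternatives in this part that used hairpins, altered tRNA reads, piRNA-length reads without near tRNA matches, shares of the piRNA-length class, or DESeq2 size factors for list medians were chosen after seeing the data; the rest were planned. With 1 library per group no replicate could be left out, and the share starting with U among genome-matched reads was not run, since no genome was used. Over the shares and 4-fold counts, 26 alternative values stayed within the counting interval or within 1.5 times the main count and 67 moved; at these depths the intervals are so narrow that small shifts count as moved, and the cause was not tested unless named. The order of the 3 libraries held in every alternative for the shares of 29 to 34 nt, 21 to 23 nt and tRNA 5′ reads and for the share starting with U. For microRNA shares it held in all but 1: among reads that match an annotated RNA, testis (6.22%) lay above sperm (4.99%).

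Counted over distinct sequences, reads of 29 to 34 nt made up 37.9% in sperm, 65.9% in testis and 2.83% in uterus, reads of 21 to 23 nt 8.76%, 2.21% and 35.1%, and the share starting with U was 55.2%, 79.8% and 22.0%. Without sequences that had a single read, the 29 to 34 nt shares were 71.1%, 80.7% and 0.366%, the 21 to 23 nt shares 6.005%, 1.26% and 81.3%, the tRNA 5′ share 36.2% in sperm and 0.547% in testis, and the microRNA shares 2.33%, 0.815% and 71.8%. Over reads of up to 35 nt, the 29 to 34 nt share was 75.5% in sperm and 79.6% in testis, and the 21 to 23 nt share 6.77% in sperm. Reads of 24 to 33 nt started with U in 59.2%, 91.4% and 19.9%, and without near tRNA matches the share was 63.9% in sperm and 91.5% in testis.

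The tRNA 5′ share was 41.9% in sperm, 0.787% in testis and 0.0438% in uterus with 1 mismatch, 58.7%, 2.81% and 0.0512% with deletions and the added G as well, 77.3%, 4.16% and 0.0316% of reads that match an annotated RNA, and 33.9% in sperm and 0.0244% in uterus from base 1 alone. The microRNA share was 1.01%, 0.545% and 45.5% for the full mature sequence, 2.25%, 0.761% and 70.7% for the first 18 bases, 86.6% in uterus among annotated reads, and 2.51%, 0.784% and 65.3% from hairpins.

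With all reads as the denominator, the 4-fold counts were 32 microRNAs higher in sperm than in testis, 12 higher in sperm and 30 in uterus, and 12 higher in testis and 43 in uterus. With DESeq2 size factors 16 were higher in testis than in sperm, 21 in sperm and 16 in uterus, and 17 in uterus against testis; with TMM factors 10 were higher in uterus than in sperm. Over all hairpin arms, of which there are more, the counts were 46 and 22 for sperm and testis, 84 and 48 for sperm and uterus, and 51 and 31 for testis and uterus. Of the list medians, 6 values under TMM factors, DESeq2 size factors or all reads as the denominator, which each shift every ratio of a pair by the same amount, changed sign from at least 4-fold. With all reads these were, for sperm over uterus erythroid to −2.92, miR-17-92 to −0.81, Hox cluster to −0.21 and negative control to −1.19, and for testis over uterus miR-17-92 to −1.70; with DESeq2 size factors erythroid turned to −0.18 for sperm over uterus. The other 102 alternative medians moved without such a change. As shares of the piRNA-length class, whose size differs between the libraries, the ratio of testis to sperm turned to 0.717 for TGGATGTGAGATAGATAGGAGAAGGAAGTC and 0.718 for Gm5878. Of the other ratios of tRNA families, sequences and genes, 17 moved and 3 stayed within their intervals.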

Other observations

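Of the tests in this part, those on the few tRNA reads in the tissues, on counting noise and on gene matches, and the comparison of gene shares, were chosen after results had been seen, while those on fragment length and 3′ trimming were set before their own results; trimming was added last, after the others. MicroRNA arms outside the list, read from annotated hairpins and named here after their values were seen, added to the difference between sperm and testis. Mir182-5p had 17319 reads in sperm, 4 in testis and 44 in uterus, a log2 ratio of sperm over testis of 11.001 (9.64 to 12.88) in reads per 1000000 hairpin reads. Mir183-5p, from the same cluster, had 4800, 6 and 35 (8.56, 7.44 to 10.01), and Mir148a-3p had 11453, 81 and 2540 (6.06, 5.75 to 6.40). In the other direction, Mir29a-3p had 764 reads in sperm and 3005 in testis (−3.06, −3.17 to −2.94) and Mir103-2-3p had 1242 and 3506 (−2.58, −2.67 to −2.48). Over all arms with at least 100 reads, 46 were at least 4-fold higher in sperm and 22 in testis, of 126.

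All annotated genes together held similar shares of the piRNA-length class in testis and sperm, 9.10% and 9.07%. Gm42418 alone held 1.40% of the class in sperm and 0.0161% in testis, so the near equality of these totals depends on this gene. Among 29 genes with a mean share of at least 0.05% of the class over both libraries, and at least 90% of their reads unique to the gene, 25 held a larger share in testis and 4 in sperm. The ratio of testis to sperm had a median of 2.05 and a 10th to 90th percentile of 0.878 to 2.77, with a median of 1.80 for the 21 noncoding and 2.54 for the 8 protein-coding genes. The 4 with a larger share in sperm, named after their values were seen, were Gm5878, 4921525O09Rik (ratio 0.897, 0.8505 to 0.947), Arhgap20 (0.803, 0.763 to 0.846) and Gm42418 (chromosome 17, 39846958 to 39848788 in GRCm38), which had 34402 reads in sperm, 3278 in testis and 72397 in uterus. The ratio of Gm42418 was 0.0115 (0.0111 to 0.0119). It held 11.9% of the class in uterus, a tissue without germ cells, so its reads need not be piRNAs. Ribosomal RNA was removed only where GENCODE annotates it as such, so ribosomal fragments under other gene names could remain in the class.

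The few 5′ tRNA reads in testis and uterus were set against 2 technical explanations. If the size window of the libraries were the whole cause, reads of one length would hold similar shares of tRNA, but with each library weighted to the sperm read lengths from 18 to 33 nt, the share in sperm, altered reads included, was 37.2 times that in testis and 67.2 times that in uterus. The uterus value is imprecise and has no interval, since that library held only 844 reads of 32 nt and 183 of 33 nt. Single lengths varied: at 27 nt the share was 23.7% in sperm and 14.8% in testis, only 1.60 times as high, and at 22 nt the ratio to testis was 7.66, while at the other lengths it was at least 12.8. Relaxing the exact match rule did not remove the difference, since with altered reads the smallest ratio, that to testis, was still 20.9. Reads with more changes, or from tRNAs outside the list, stay uncounted, so the match rule is not excluded as a cause. A difference between mature sperm and the tissues remains as a hypothesis, with 1 library each.

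Single piRNA-length sequences differed unequally between the libraries: over the 1000 most abundant testis sequences of the class, the log2 ratio of sperm over testis in RPM (0.5 counts added to sperm) had a median of −6.56 and an SD of 2.80, and 67 had 0 reads in sperm, while the 1000 most abundant in sperm had a median of 3.65. The sign of the median thus went with the library used for the ranking. Fragment length did not account for the spread, since the pooled SD within single lengths was 0.997 of the whole. Summing sequences of the class with the same first 20 bases left an SD of 0.919 of that of single sequences. The median was then −5.86, against −6.56 for single sequences. Trimming at the 3′ end within the lengths of the class thus did not account for most of the spread. Reads trimmed to lengths outside the class were not summed, so 3′ trimming as a whole stays open. The SD of single sequences was 20.1 times that expected from counting, which decides nothing with 1 library of amplified reads per group. A split by gene match decides nothing either, as 913 of the 1000 sequences had no match (pooled SD 1.001 of the whole; medians of −6.62 without a match, −6.55 with a unique gene and −5.65 for the rest). Unequal ligation or amplification and a selective loss during sperm maturation remain possible and were not tested.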
